A study of Homo sapiens with 6 samples.

How the data were processed

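Messenger RNA was measured in 6 libraries of the HT-29 human colorectal cancer cell line with DOX-inducible ZEB1: 3 clones without DOX (mDOX) and the same 3 clones with DOX for 48 hours (pDOX). The abbreviations mDOX and pDOX were read as minus and plus DOX from the series' own design text. Per the labels' protocols, total RNA came from a Nucleospin RNA Plus extraction and libraries were made with the QuantSeq 3' mRNA-Seq FWD kit of Lexogen, which primes at the poly(A) tail, so that a gene's count comes from its 3' end and does not grow with its length. The authors deposited 1 table of raw counts per gene and library: the values are whole numbers with a different total in each library. The genome build GRCh38 and the tool DESeq2 are named in the submitters' processing notes. The aligner, the counting tool, the annotation release, the strand setting and any use of molecular identifiers are not given in the sources used here.

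The table had 27269 rows, of which 5 carried neither a gene ID nor a value and were left out. Of the 27264 genes, 26914 were given a symbol from their Ensembl ID, and 3973 had no count in any library. Coordinates and gene types were taken from GENCODE release 29 on GRCh38. Library totals ranged from 6225188 to 7756644 counts. CPM (counts-per-million) values were computed with edgeR on library sizes scaled by TMM factors, which lay between 0.942 and 1.04, and 3 counts, the floor used for detection, stood for 0.379 to 0.513 CPM. Counting intervals are exact 95% intervals and cover counting error only, since copies made by PCR are not independent molecules. The 10 most abundant genes took between 7.21% and 7.92% of the counts of a library. The libraries of a group were compared in pairs by a chi-square test over genes and all differed by more than sampling noise, so each was kept as a replicate.

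The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with the group as the only term, TMM scaling, robust dispersion, and the default expression filter by group (a minimum count of 10 and a minimum total of 15), which left 11631 genes. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05, and the standard error of a log2 change was taken from the F statistic. The design did not use the clone as a term. The clone number in the labels names the same clone with and without DOX, and the deviations of the libraries from their group means correlated at 0.514, 0.499 and 0.553 between the libraries of a clone, with a highest value of -0.211 between libraries of different clones. The deviations of a group cancel out over its 3 libraries, so positive values within clones make those between clones negative. Because of the shared clones, a fit with the clone as a block was set beside each result whose call or count it changed. The replicates of a group are independent clones.

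Gene lists for epithelial, mesenchymal, signaling, cell cycle, metabolic, control and other cell type genes, 30 in all, were fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings. The list of genes repressed by ZEB1 was drawn from general knowledge of the field and not from these libraries. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, with camera at an estimated correlation and with fry, on log2 CPM with a prior count of 2, and P-values were adjusted over the 28 lists with tested members. Changes within a clone used the same log2 CPM. Genes were also adjusted over each list alone. Named genes were ZEB1, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM, the same direction in all clones and a symbol, and the 4 members of each list with the smallest p. Genes outside this rule are named as chosen after their values were seen, or as members of a list or a called group. Some genes that met the rule are not reported here by name, and counts of genes and of lists include them. Low genes with a few counts are given as pooled ratios with an interval.

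Alternatives were DESeq2 1.42.0 with and without the block, DESeq2 size factors, limma-voom, no expression filter, a filter of at least 10 CPM in 3 libraries, leaving out each library and each clone, and, chosen after seeing the data, total counts without TMM factors and the block without each clone in turn. The scripts were tested on simulated counts with the real library sizes and the fitted gene means without the DOX effect, with 200 changed genes among 11296 tested. Each changed gene had the same fold in all 3 clones. The real changes were smaller in clone 3, so the rates may differ there. Without the block, 1.49%, 22.4% and 87.9% of genes changed by 1.5, 2 and 4-fold were recovered and 0% of the calls were unchanged genes. With the block, 43.3%, 89.6% and 98.5% were recovered and 8.88% of the calls were unchanged genes. In the simulated test among clones, over 11156 genes, 99.5% of genes changed by 4-fold were recovered and 11.6% of the calls were unchanged genes. There the only differences between clones were the changed genes of clone 2. Genes that overlap another gene (KRT18 and KRT8, OVOL2 and SNX5, TGFB1 and HNRNPUL1, LGR5 and TSPAN8) and near-identical copies (TUBA1A and other tubulins, IFITM2 and IFITM3) are uncertain, since the counting of shared or antisense reads is not known. Figures were drawn with matplotlib 3.10.9.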

Results

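Gene expression was measured in HT-29, an epithelial cell line from a human colorectal cancer, that carried ZEB1 under the control of doxycycline (DOX). ZEB1 is a zinc-finger transcription factor that represses epithelial genes during epithelial-to-mesenchymal transition (EMT), a change in which epithelial cells lose their cell contacts and gain motile properties. The cells came from 3 independent clones, each kept without DOX (mDOX) or with DOX (pDOX) for 48 hours, so each group held 3 libraries and each clone gave 1 library to each group. The libraries were made with a 3' mRNA kit that reads near the end of each transcript. They held 6225188, 6801356 and 6309850 counts for clones 1, 2 and 3 without DOX, and 6923254, 7391984 and 7756644 with DOX, so the pDOX library was the deeper in each clone. In CPM (counts scaled to the library total, with TMM factors), a floor of 3 counts corresponded to between 0.379 and 0.513 CPM. In a principal component analysis, the component with 45.2% of the variance had negative scores in the 3 mDOX libraries and positive scores in the 3 pDOX libraries, while the components with 23.5% and 20.3% separated the clones.

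ZEB1, the gene that DOX was meant to induce, was higher with DOX in all 3 clones. ZEB1 (ENSG00000148516, chromosome 10, 31318495 to 31529814, GRCh38) went from 3.42 to 76.8 CPM in clone 1, from 5.33 to 215 CPM in clone 2 and from 6.91 to 71.5 CPM in clone 3, which are folds of 22.5, 40.4 and 10.3. Behind these values lay 20, 35 and 44 counts without DOX and 553, 1612 and 565 counts with it. The group means were 5.22 ± 1.75 CPM without DOX and 121 ± 81.6 CPM with DOX (SD, n = 3), a log2 change of 4.53 (SE 0.54, edgeR quasi-likelihood test, adjusted p = 0.0162). ZEB1 was no longer called by edgeR when the mDOX library of clone 1 (adjusted p = 0.0963) or of clone 2 (0.104) was left out, with log2 changes of 4.30 and 4.52. Counts of the transgene and of the resident gene were not told apart here. With a 3' kit, a transgene that lacks the 3' untranslated end of ZEB1 may not be counted as ZEB1. These counts may therefore not give the level of the transgene.

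The question of the design was what ZEB1 does to the transcriptome of these cells. No cells without the transgene were treated with DOX, so effects of ZEB1 and of DOX itself are not told apart in any result here. Among the genes that rose most were EMP3, a tetraspan membrane protein, from 1.41 ± 0.785 to 37.0 ± 15.7 CPM (SD, n = 3), and LGALS1, the secreted lectin galectin-1, from 8.99 ± 4.26 to 97.2 ± 20.8 CPM. BMF, a pro-apoptotic BH3-only protein, rose from 4.51 ± 2.78 to 38.2 ± 23.2 CPM. Among the genes that fell most, the calcium-binding protein S100A14 went from 91.9 ± 49.3 to 4.59 ± 5.23 CPM, the epithelial clathrin adaptor subunit AP1M2 from 61.1 ± 9.37 to 5.65 ± 5.60 CPM, and the membrane protein TMEM125 from 85.5 ± 16.7 to 4.69 ± 3.56 CPM. In all, 292 of the 11631 tested genes changed (edgeR quasi-likelihood test, adjusted p under 0.05): 170 rose, 141 of them by more than 2-fold, and 122 fell, 87 of them by more than 2-fold. All 292 moved in the same direction in the 3 clones. A gene can hardly pass this test otherwise, so this is no independent sign that the clones agree. Over all tested genes, between 71.5% and 72.0% moved in the same direction in a pair of clones.

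The other genes of largest rise were DLL3, a Notch ligand, ATOH8, a basic helix-loop-helix factor, and the tubulin TUBA1A. DLL3 had 1 count over the 3 mDOX libraries and 264 over the 3 pDOX libraries, 201 of them in clone 3, a scaled ratio of 219 (95% counting interval 39.1 to 8701). ATOH8 had 8 and 289 counts, a ratio of 30.0 (15.0 to 70.2). TUBA1A had a log2 change of 4.39 (SE 0.83, adjusted p = 0.0492) that did not pass with the clone as a block (adjusted p = 0.120), and near-identical tubulin genes could share its counts. The other genes of largest fall were TMPRSS4, a transmembrane serine protease, PDE4C, a cAMP phosphodiesterase, TMEM30B, TMC4 and BSPRY. TMPRSS4 had 274 counts without DOX and 5 with it, all 5 in clone 3, a ratio of mDOX to pDOX of 65.9 (27.9 to 205), and PDE4C 190 and 9 counts, 8 of the 9 in clone 3, a ratio of 25.4 (13.1 to 56.4). The log2 changes of TMEM30B, TMC4 and BSPRY were -3.81, -3.56 and -3.31. TMEM125 and TMEM30B overlap other annotated genes, and the strand setting of the counting was not given in the sources used here.

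**Figure D1:**
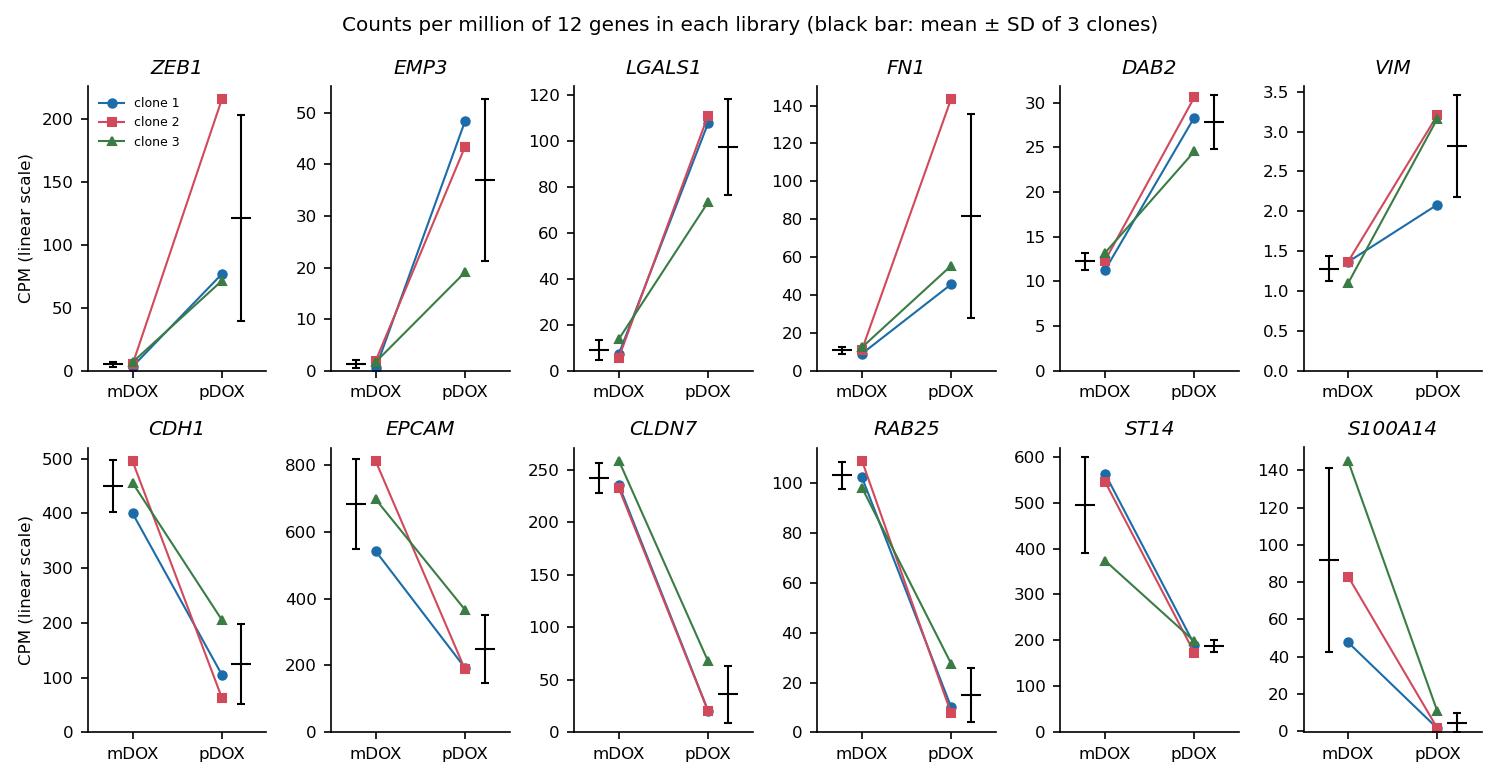
CPM (TMM-scaled, linear axis) of 12 genes in the mDOX and pDOX library of each clone, joined by a line per clone, with the mean and SD of the 3 clones beside each group in black. ZEB1 and the genes of the upper panels were higher with DOX in each clone, with VIM between 1.28 and 2.82 CPM on average, and CDH1 and the genes of the lower panels were lower, with CDH1 between 450 and 125 CPM.

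The count of changed genes depended on whether the clones were compared each with itself. With the clone number as a block, 2638 genes changed (1410 rose and 1228 fell, 735 of all by more than 2-fold), and 286 of the 292 genes were among them, all in the same direction. Without the block, single libraries moved the count: it was 0 without the mDOX library of clone 1 (2082 genes at an unadjusted p under 0.05), 13 without the pDOX library of clone 1, 5 without the mDOX library of clone 2, 28 without the pDOX library of clone 2 and 109 without the mDOX library of clone 3. Without the pDOX library of clone 3 it was 431, and without both libraries of clone 3 it was 135. The split of rises and falls moved too: 206 rose and 225 fell without the pDOX library of clone 3, 53 rose and 82 fell without clone 3, and 181 rose and 88 fell with total counts in place of TMM scaling.

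Epithelial genes were among those that fell. Of 28 tested genes of cell junctions and polarity, 9 fell and none rose, and 18 fell when adjusted over the list alone; 17 fell and 1 rose with the clone as a block. RAB25, a small GTPase of epithelial recycling endosomes, had 103 ± 5.49 CPM without DOX and 15.1 ± 10.9 CPM with it (SD, n = 3; adjusted p = 0.0306 by edgeR, 0.0566 with the block). CDS1, a CDP-diacylglycerol synthase, fell by 2.05 on the log2 scale, the tight-junction protein MARVELD3 by 2.60, the polarity protein LLGL2 by 1.63 and EPCAM, an epithelial adhesion molecule named after its values were seen, by 1.45. E-cadherin, CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548), the best-known target of ZEB1 and also named after its values were seen, averaged 450 ± 47.8 CPM without DOX and 125 ± 73.0 CPM with it, but did not pass (log2 change -1.85, SE 0.38, adjusted p = 0.0518 by edgeR, 0.0881 with the block). It was lower with DOX in each clone, by 1.92, 2.96 and 1.15 on the log2 scale in clones 1, 2 and 3. By DESeq2 the adjusted p of CDH1 was 9.2e-06, and by limma-voom 0.0328.

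Of 14 desmosome and keratin genes, 3 fell (11 when adjusted over the list alone, 12 with the block): plakophilin PKP3, from 438 ± 120 to 94.1 ± 24.7 CPM (SD, n = 3), and the keratins KRT80 and KRT20, with log2 changes of -1.22 and -0.76 (adjusted p = 0.0515 and 0.0571 with total counts). KRT18 had a log2 change of -0.97 (adjusted p = 0.0514 by edgeR, 2.5e-04 with the block). Of 16 epithelial transcription and splicing factors, 1 fell, the splicing regulator ESRP2, from 10.5 ± 1.22 to 3.55 ± 1.20 CPM; 9 fell when adjusted over the list alone and 12 with the block. GRHL2, a grainyhead factor of epithelial cells, had 49.3 ± 16.3 and 7.66 ± 5.28 CPM (adjusted p = 0.0532 by edgeR, 2.8e-04 with the block). Of 10 epithelial surface proteases and their inhibitors, 4 fell (8 when adjusted over the list alone, 7 with the block), among them the membrane protease matriptase, ST14, from 494 ± 105 to 188 ± 12.9 CPM, and the kallikrein KLK6, with a log2 change of -1.83. KLK10, with a log2 change of -1.91, had an adjusted p of 0.0401 by edgeR and of 0.0661 with the block.

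A further list held genes known from the literature to be repressed by ZEB1, and 20 of its 24 tested members also stood in another list. Of the 24, 12 fell, 22 fell when adjusted over the list alone and 21 with the block, and all 24 were lower with DOX in each of the 3 clones. The median log2 changes were -1.69 for this list, -1.55 for the proteases, -0.94 for junctions and polarity, -0.71 for the transcription and splicing factors and -0.67 for desmosomes and keratins. When a single library was left out, the number of genes that fell ranged from 0 to 18 in the ZEB1-repressed list (21 to 24 at an unadjusted p under 0.05), 0 to 4 for the proteases, 0 to 15 for junctions and polarity, 0 to 4 for the transcription and splicing factors and 0 to 2 for desmosomes and keratins. In clone 3 these medians were nearer 0 than in clones 1 and 2: that of the ZEB1-repressed list was -1.84, -2.55 and -1.21 in clones 1, 2 and 3. Against the other genes, camera with a preset correlation of 0.01 gave adjusted p-values of 1.1e-22, 1.3e-07, 1.8e-11, 3.8e-06 and 2.7e-09 in that order of lists. None of the 5 passed with an estimated correlation, where the adjusted p-values were 0.228, 0.225, 0.248, 0.259 and 0.225. That setting takes its degrees of freedom from the 6 libraries and so has little power. Missing the threshold there does not show that these lists did not change.

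**Figure D2:**
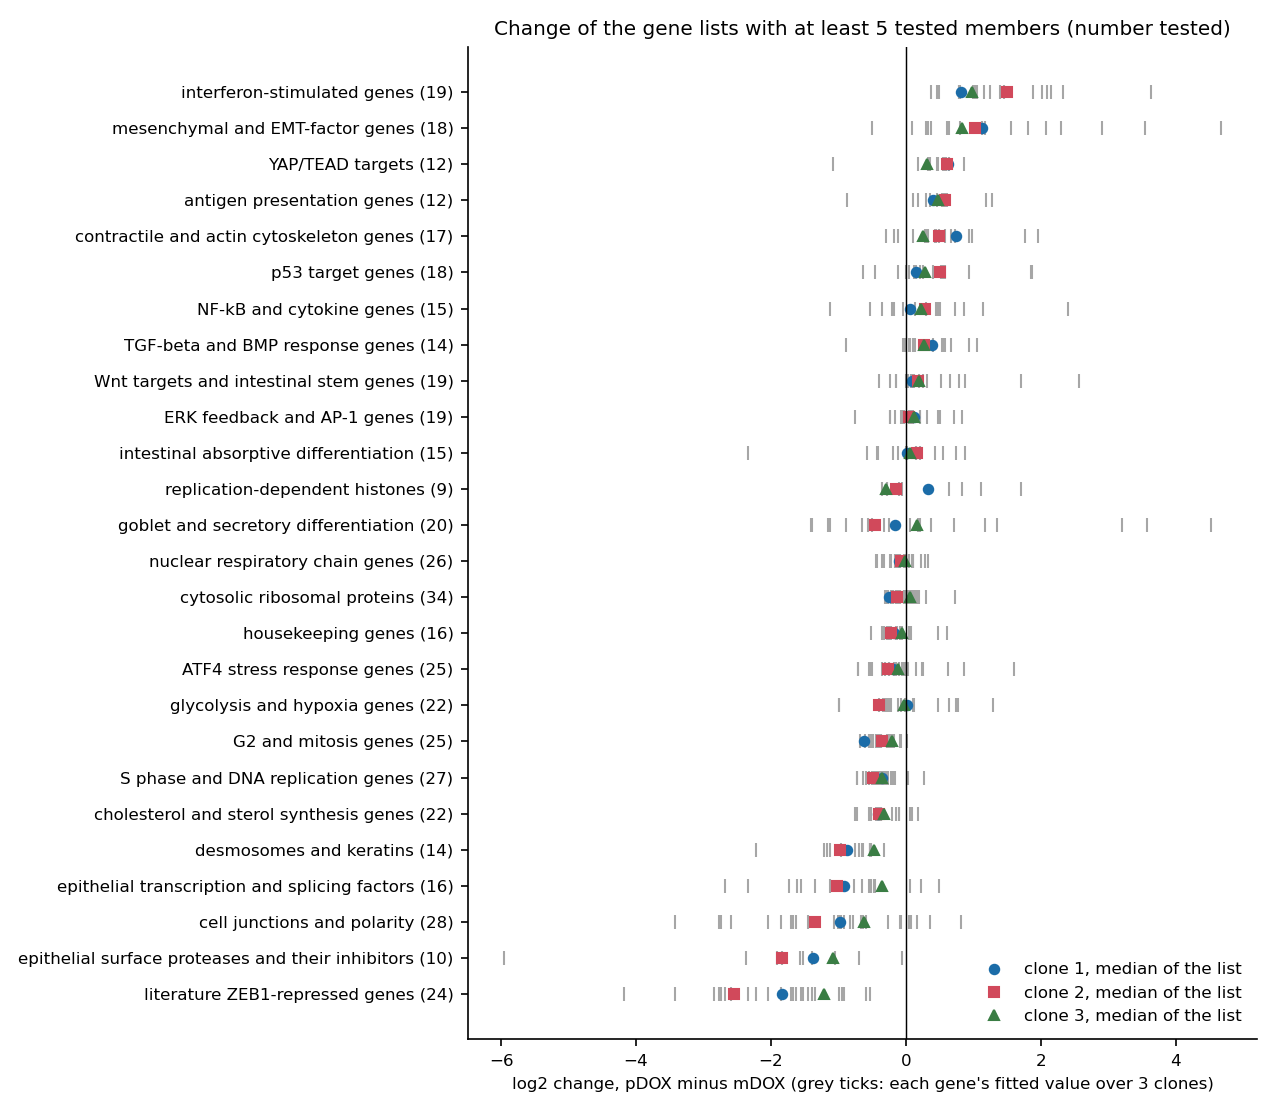
Log2 change (pDOX minus mDOX) of the members of 26 gene lists with at least 5 tested members, with the number tested in parentheses; grey ticks are single genes over the 3 clones, and the colored symbols are the median of the list in each clone. The ZEB1-repressed list has the lowest median (-1.69) and the interferon-stimulated list the highest (1.16).

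Mesenchymal genes rose in part. Of 45 mesenchymal and EMT-factor genes, 40 had a row and 18 had enough counts to be tested. Of the 18, 5 rose and none fell. When adjusted over the list alone 10 rose, with the clone as a block 13, and 16 were higher in each of the 3 clones. With a single library left out, between 0 and 5 rose (9 to 12 at an unadjusted p under 0.05). Besides EMP3, the 5 included fibronectin, FN1, from 10.9 ± 1.69 to 81.6 ± 53.9 CPM (SD, n = 3), the endocytic adaptor DAB2, from 12.3 ± 0.962 to 27.8 ± 3.06 CPM, and the matrix protein TGFBI, with a log2 change of 1.80. Vimentin, VIM, named after its values were seen, stayed low: it had 1.28 ± 0.155 CPM without DOX and 2.82 ± 0.636 CPM with DOX (log2 change 1.13, adjusted p = 0.137 by edgeR, 0.0527 with the block). The other EMT factor genes ZEB2, SNAI2 and TWIST1 had too few counts to be tested, with 1, 0 and 0 counts over the 3 pDOX libraries. None of these factors rose to a level that could be tested, and smaller changes in them were not detectable at this depth. Other untested members included CDH2, SPARC, MMP2 and COL3A1, with 0, 2, 0 and 1 counts with DOX. Among the untested, TNC went from 18 to 92 counts, with 74 in a single library, and COL6A1 from 0 to 20. The list results below cover the tested members only. The median log2 change of the list was 0.97, and 0.57 without the pDOX library of clone 1 (camera adjusted p = 1.9e-07; adjusted p = 0.0776 with an estimated correlation).

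Genes of the contractile cytoskeleton and of YAP/TEAD, a transcriptional pair that responds to cell tension and contact, were higher with DOX on average. Of 17 contractile and actin cytoskeleton genes, none passed by edgeR (7 at an unadjusted p under 0.05, 5 by DESeq2), while 6 rose when adjusted over the list alone and 8 with the block. Of these, myosin light chain MYL9 had 0.816 ± 0.482 and 3.19 ± 0.747 CPM (SD, n = 3) and talin, TLN1, 61.1 ± 4.47 and 101 ± 27.1 CPM. Of 12 YAP/TEAD targets, none passed by edgeR (7 at an unadjusted p under 0.05, 0 by DESeq2), while 4 rose when adjusted over the list alone, and 6 rose and 1, F3, fell with the block. CCN1, a matricellular protein, had 28.0 ± 2.73 and 42.6 ± 6.70 CPM. The median log2 changes were 0.45 and 0.51, and camera gave an adjusted p of 0.0018 for both lists, against adjusted p-values of 0.439 and 0.216 with an estimated correlation. Of 14 TGF-beta and BMP response genes, 1 rose, SKIL, a feedback repressor of SMAD signaling, with a log2 change of 0.67; 2 rose and 1 fell when adjusted over the list alone, and 5 rose and 1 fell with the block. The median of that list was 0.27 (camera adjusted p = 0.0639).

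Intestinal differentiation genes moved both ways. Of 20 goblet and secretory genes, 1 rose and 1 fell, against 4 and 1 when adjusted over the list alone and 5 and 7 with the block. FCGBP, a mucus protein, rose from 5 to 150 counts over 3 libraries each, a ratio of 24.9 (95% counting interval 10.5 to 77.9), and GALNT12, an enzyme of mucin-type O-glycosylation, fell by 1.40 on the log2 scale (adjusted p = 0.0532 with total counts). The trefoil peptides TFF3 and TFF2 had log2 changes of 3.58 and 3.21 (adjusted p = 0.0591 and 0.0857 by edgeR, 8.2e-06 and 4.9e-04 with the block). The median of the goblet list was -0.09, its mean 0.36, and camera called it up with an adjusted p of 0.712; with single libraries left out the median ran from -0.21 to 0.23. Of 15 absorptive differentiation genes, none passed by edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2); 1 fell when adjusted over the list alone, villin, VIL1, with a log2 change of -2.34, and 3 rose and 2 fell with the block. The absorptive list had a median of 0.02, a mean of -0.06 and a camera direction of up (adjusted p = 0.906), and its median ran from -0.12 to 0.11 with single libraries left out. Of 19 Wnt targets and intestinal stem cell genes, none passed by edgeR, over all genes or over the list alone (4 at an unadjusted p under 0.05, 1 by DESeq2), while 5 rose and 1 fell with the block. The stem cell marker LGR5 had 3.87 ± 2.04 and 12.7 ± 6.81 CPM (SD, n = 3; adjusted p = 0.135 by edgeR, 1.4e-04 with the block), and the camera test of the list had an adjusted p of 0.232.

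Some cell cycle genes fell, by small amounts. Of 27 genes of S phase and DNA replication, 4 fell and none rose: the clamp loader subunits RFC2 and RFC3, the origin licensing factor CDC6 and the helicase subunit MCM4. MCM4 went from 331 ± 15.8 to 219 ± 9.48 CPM (SD, n = 3) and RFC3 from 71.2 ± 7.73 to 43.2 ± 1.75 CPM. None fell with total counts in place of TMM scaling (10 genes of the list at an unadjusted p under 0.05) or when any single library was left out (between 11 and 15). In that list 9 genes fell when adjusted over the list alone and 16 with the block, and the median log2 change was -0.40 (camera adjusted p = 2.8e-08; adjusted p = 0.0776 with an estimated correlation). Of 25 genes of G2 and mitosis, 1 fell, the mitotic kinase AURKB, from 258 ± 11.6 to 161 ± 19.4 CPM; the count was also 1 when adjusted over the list alone, and 13 fell with the block. With total counts none fell (9 at an unadjusted p under 0.05), and none when any single library but the pDOX library of clone 3 was left out (between 7 and 9). The median log2 change was -0.40 (camera adjusted p = 2.2e-07; adjusted p = 0.413 with an estimated correlation).

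In metabolism, cholesterol synthesis genes were lower with DOX in each clone. Without the clone as a block, the size of the fall moved with single libraries. Of 22 cholesterol and sterol synthesis genes, none passed by edgeR over all genes or over the list alone (5 at an unadjusted p under 0.05, 2 by DESeq2), and 11 fell with the clone as a block. The median log2 change of the list was -0.41 (camera adjusted p = 0.0018, and 0.560 with an estimated correlation). Within clones 1, 2 and 3 the median was -0.41, -0.40 and -0.32. In all 3 clones 15 of the 22 genes were lower and 0 higher. With no block, the list median was -0.09 without the mDOX library of clone 2 (camera adjusted p = 0.116) and -0.65 without the pDOX library of that clone. It was -0.26 without the pDOX library of clone 3 (camera adjusted p = 0.0503). Such fits leave a clone unpaired, and 14 of the 22 genes differed among clones. Of 22 glycolysis and hypoxia genes, none passed by edgeR (5 at an unadjusted p under 0.05, 3 by DESeq2), 1 rose when adjusted over the list alone, and 4 rose and 3 fell with the block. Of 26 nuclear genes of the respiratory chain, none passed by edgeR, over all genes or over the list alone (3 at an unadjusted p under 0.05, 0 by DESeq2), and 1 rose and 4 fell with the block. The camera adjusted p-values of these lists were 0.520 and 0.243.

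Interferon-stimulated genes, a set of antiviral effectors, were higher with DOX within each clone, on levels that differed widely between clones. Of 19 tested, none passed by edgeR, over all genes or over the list alone (1 at an unadjusted p under 0.05, 0 by DESeq2), whereas 15 rose and none fell with the clone as a block. The median log2 change was 1.16, and 18 of the 19 were higher with DOX in all 3 clones, with medians of 0.81, 1.49 and 0.98 in clones 1, 2 and 3. Without the block, the libraries of clone 3 moved the median, to 0.07 without its pDOX library (camera adjusted p = 0.202) and to 2.44 without its mDOX library. IFI6 went from 2.90 to 8.89 CPM in clone 1, from 2.29 to 16.4 in clone 2 and from 30.2 to 154 in clone 3. IFI27 went from 0.854 to 3.33, from 0.609 to 4.01 and from 21.7 to 87.0 CPM in the same order. MX1 was near the floor of 3 counts in clone 1, at 0.513 and 0.556 CPM, and went from 8.80 to 40.1 CPM in clone 3. Fitted with the block and without clone 3, 9 of 16 tested members rose and none fell. Camera gave an adjusted p of 0.0018, and the adjusted p with an estimated correlation was 0.561.

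**Figure D3:**
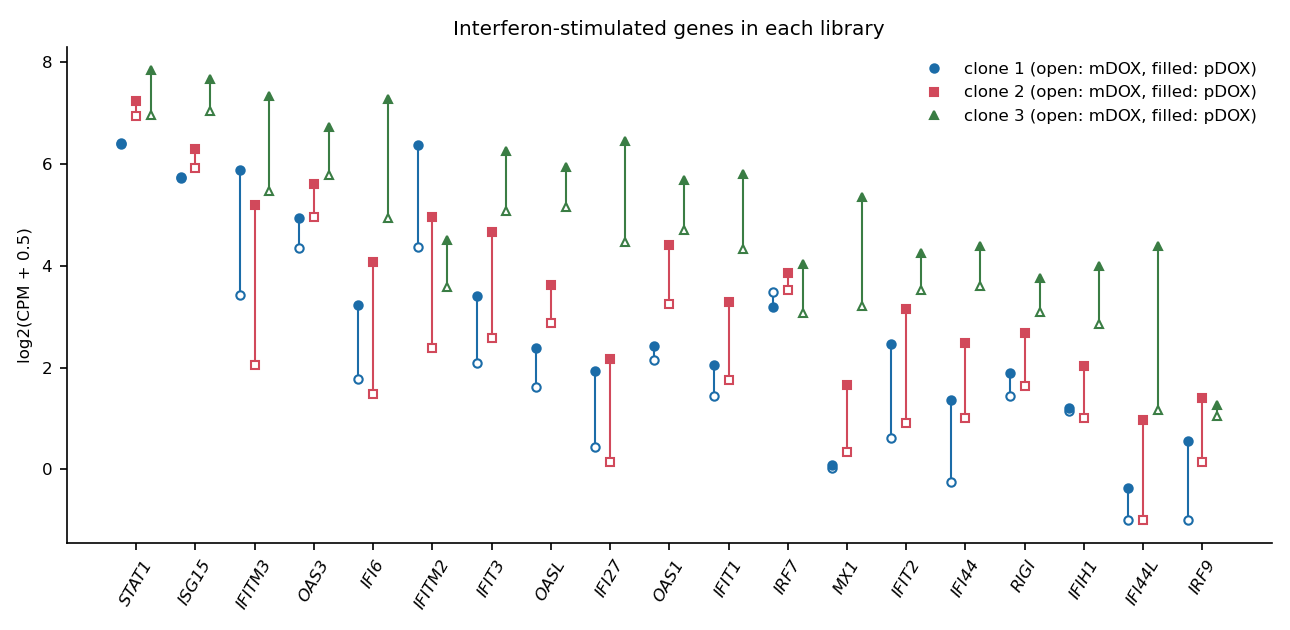
Level of 19 interferon-stimulated genes in each library, as log2 of CPM plus 0.5, with an open symbol for mDOX and a filled symbol for pDOX of the same clone joined by a line. Clone 3 has the highest mDOX level in 17 of the 19 genes, and 18 of the 19 genes are higher with DOX in all 3 clones.

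Other signaling groups changed in few members. Of 12 antigen presentation genes, 1 rose, the non-classical class I gene HLA-E, from 42.9 ± 9.54 to 104 ± 6.94 CPM (SD, n = 3); 2 rose when adjusted over the list alone and 5 with the block, and camera gave an adjusted p of 0.0328 (adjusted p = 0.561 with an estimated correlation, 0.0690 with total counts, and 0.0954, 0.356 and 0.342 without the mDOX library of clone 1, that of clone 2 and the pDOX library of clone 3). Of 18 p53 targets, 1 rose, TP53INP1, from 2.70 ± 1.06 to 9.91 ± 2.19 CPM; 3 rose when adjusted over the list alone, and 4 rose and 2 fell with the block. The camera adjusted p of the p53 list was 0.0586, and 0.0316 with the block (adjusted p = 0.560 with an estimated correlation, 0.511 with that and the block). Of 19 ERK feedback and AP-1 genes, 1 rose, the ETS factor ETV5, with a log2 change of 0.72, both over all genes and over the list alone, and 3 rose with the block. Of 15 NF-kB and cytokine genes, none passed by edgeR (4 at an unadjusted p under 0.05, 3 by DESeq2), 2 rose and 1 fell when adjusted over the list alone, and 3 rose and 2 fell with the block. Of 25 ATF4 stress response genes, none passed by edgeR (4 at an unadjusted p under 0.05, 2 by DESeq2), 1 fell when adjusted over the list alone, and 1 rose and 7 fell with the block. The ATF4 target SLC7A5, an amino acid transporter, had 317 ± 26.0 and 195 ± 29.7 CPM (adjusted p = 0.0520 by edgeR, 0.0011 with the block). Camera gave adjusted p-values of 0.311, 0.423 and 0.129 for the ERK, NF-kB and ATF4 lists.

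Control groups moved little. None of 34 cytosolic ribosomal protein genes passed by edgeR, over all genes, over the list alone or with the block (0 at an unadjusted p under 0.05, 0 by DESeq2), and their median log2 change was -0.11 (-0.03 with total counts). None of 16 housekeeping genes passed by edgeR, over all genes or over the list alone (2 at an unadjusted p under 0.05, 1 by DESeq2), and 1, B2M, rose and 2 fell with the block. None of 9 replication-dependent histone genes passed by edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2); 1 rose when adjusted over the list alone and 2 with the block, the median of the list was -0.05 (0.03 with total counts in place of TMM scaling, -0.12 to 0.22 with single libraries left out), its mean 0.36 and its camera direction up (adjusted p = 0.423). The camera adjusted p was 0.289 for both the ribosomal and the housekeeping list. Of markers of other cell types, no fibroblast or stromal marker had enough counts to be tested, and the 6 that had a row, 2 of which are also mesenchymal genes, held 17 counts over the 3 mDOX libraries and 64 over the 3 pDOX libraries, of which LUM gave 48, with 39 in a single library. Of 2 tested leukocyte markers, LYZ and CD14, none passed by edgeR over all genes (1 at an unadjusted p under 0.05, 0 by DESeq2; 1, LYZ, when adjusted over the list alone) or with the block. Of 2 tested endothelial markers, ENG, a TGF-beta co-receptor, rose by a log2 change of 1.48 and ESAM, with 113 ± 36.8 and 71.6 ± 7.17 CPM (SD, n = 3), had -0.66, which passed over the list alone and with the block; camera gave adjusted p-values of 0.232 and 0.627 for these lists. None of the 13 mitochondrially encoded mRNAs was analysed here.

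Of 28 lists tested with camera, 13 passed, 5 up and 8 down, and none passed with an estimated correlation (6 at an unadjusted p under 0.05). With 6 libraries that setting had little power, whatever the correlation. The mesenchymal list had an estimated correlation of -0.017, below the preset 0.01. Its unadjusted camera p still went from 4.0e-08 to 0.0040. Of the 13 lists, the YAP/TEAD list was also below the preset, at -0.043, and the S phase list was at 0.018. The others ran from 0.207 for the contractile list to 0.676 for the interferon-stimulated list. For those the preset is low, so their camera p-values at the preset correlation can be too small. By fry, a test of whether the genes of a list move on balance in a direction, 9 passed: 8 of the 13, and the leukocyte list with its 2 tested genes (adjusted p = 0.0071). The contractile, G2, cholesterol, interferon-stimulated and antigen presentation lists did not pass by fry, with adjusted p-values of 0.1004, 0.0850, 0.339, 0.378 and 0.339. Splits of the libraries that cut across the treatment gave up to 16 lists by camera at the preset correlation. The median, the mean and the camera direction differed in sign for 3 lists, those of absorptive, goblet and histone genes.

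The 292 changed genes moved in the same direction in the 3 clones but not to the same extent. Clone 3 had the smallest change of the 3 clones in 242 of the 292 changed genes, against 30 for clone 1 and 20 for clone 2. The median log2 change of the genes that fell was -1.59, -1.68 and -0.94 in clones 1, 2 and 3, and that of the genes that rose was 1.65, 1.61 and 1.12. RAB25 was lower by 3.30 and 3.79 on the log2 scale in clones 1 and 2 and by 1.82 in clone 3. Across the 292 genes, which are not independent replicates, the slope of the change in clone 3 on that in clone 1 was 0.67 and on that in clone 2 0.64, and that of clone 2 on clone 1 was 1.02. Over all 11631 tested genes these slopes were 0.42, 0.44 and 0.66. Across all 11631 tested genes, the changes of a pair of clones had a Pearson correlation between 0.652 and 0.678 and a Spearman correlation between 0.577 and 0.595, with between 71.5% and 72.0% of genes moving in the same direction. With 1 library per clone and condition, the difference in response between clones was not tested gene by gene.

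**Figure D4:**
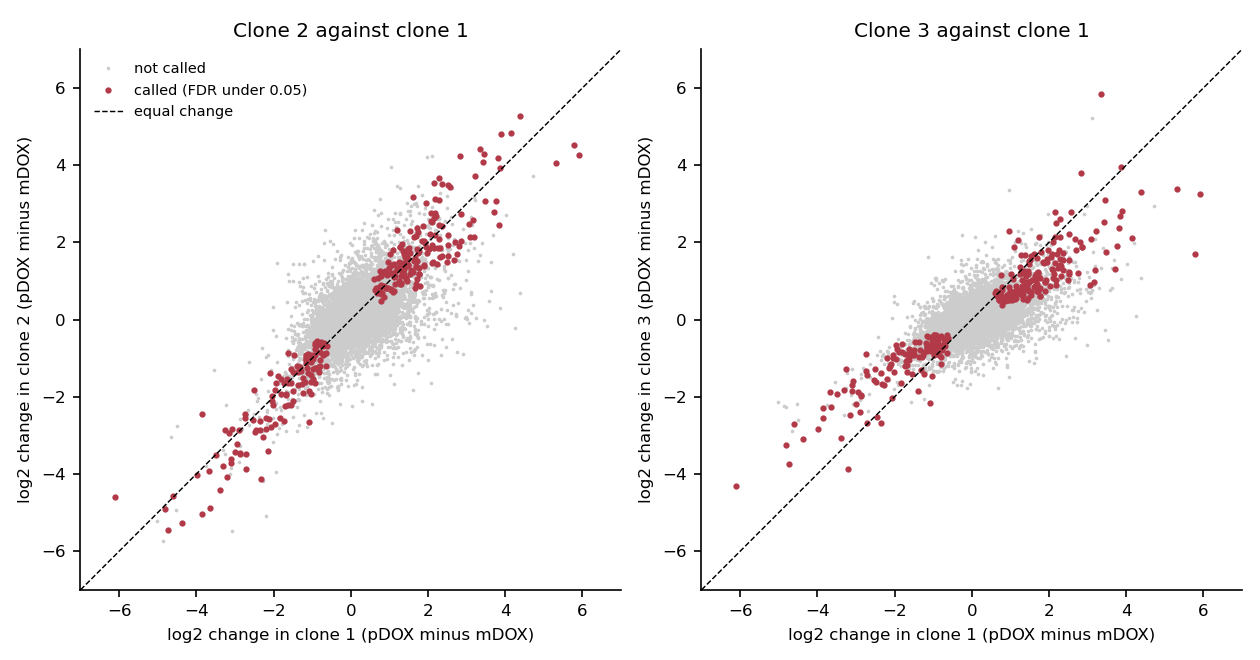
Log2 change with DOX (pDOX minus mDOX) of each tested gene in clone 2 and in clone 3 against that in clone 1, with the 292 changed genes in red and a dashed line of equal change. The changed genes follow the line in clone 2 (slope 1.02) and lie nearer 0 in clone 3 (slope 0.67).

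The clones also differed from each other whatever the treatment. SPINK1, a secreted trypsin inhibitor, had 391 and 179 CPM in the mDOX and pDOX libraries of clone 1, 12.5 and 3.61 in clone 2, and 26.1 and 13.5 in clone 3. GABRA3, a GABA receptor subunit, had 7.01, 0.152 and 41.6 CPM in the mDOX libraries of clones 1, 2 and 3, and the receptor kinase AXL had 22.4, 2.59 and 1.41 CPM; these were named after their values were seen. In an edgeR quasi-likelihood test of the clone terms, 1641 of the 11631 genes differed among clones (3320 at an unadjusted p under 0.05). They included 14 of the 292 genes changed by DOX, 604 of the 2638 genes that changed with the clone as a block, and 17 of the 19 interferon-stimulated genes. The median interferon-stimulated gene was higher in clone 3 than in clone 1 by 2.62 on the log2 scale. Of the other lists, 14 of 22 cholesterol synthesis genes and 11 of 20 goblet and secretory genes differed among clones, against 3 of 27 S phase genes.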

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

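The difference between clones in the items of this part was not tested, since each clone gave 1 library per condition, and each is given because the median of a list had opposite signs in the clones. The median log2 change of the goblet and secretory genes was -0.17 and -0.45 in clones 1 and 2 and 0.16 in clone 3, a range of 0.61. That of the glycolysis and hypoxia genes was 0.02 in clone 1, -0.40 in clone 2 and -0.03 in clone 3, a range of 0.42. The cytosolic ribosomal protein genes had medians of -0.25, -0.12 and 0.07 in clones 1, 2 and 3, a range of 0.31. The replication-dependent histone genes had medians of 0.33, -0.15 and -0.30, a range of 0.62.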

How the results depend on the processing

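The count of changed genes was 292 in the main analysis. It was 2638 with the replicate block, 887 with DESeq2, 1550 with DESeq2 and the block, and 1087 with no expression filter; with DESeq2 size factors, limma-voom, the stricter filter and total counts it was 290, 295, 239 and 269. Leaving out a library or both libraries of a clone, the count ranged from 0 to 431: 0 without the mDOX library of clone 1 (2082 at an unadjusted p under 0.05), 0 without clone 1 (1618), 0 without clone 2 (1357) and 135 without clone 3. Fitted with the block, chosen after seeing the data, it was 2197, 1839 and 1949 without clones 1, 2 and 3, and held 283, 289 and 292 of the 292 genes. The cause of the counts with libraries left out was not tested. No gene of the 292 changed sign under any of these settings in which it was tested. The log2 change of ZEB1 ranged from 3.82 to 5.03 when libraries or clones were left out without the block. It missed the threshold without the mDOX library of clone 1 (4.30, adjusted p = 0.0963) or of clone 2 (4.52, 0.104), without clone 1 (4.53, 0.209) and without clone 2 (3.83, 0.113), and passed in the others; the adjusted p over all settings ran from 3.8e-28 to 0.209. The number of gene lists called was 13, and 0 with an estimated correlation (6 at an unadjusted p under 0.05), 9 with fry, 0 with the block and an estimated correlation (1 at an unadjusted p) and 0 with the block and fry (16 at an unadjusted p); in the other settings it ranged from 11 to 16. By camera at the preset correlation, the block ended no list call and added only that of the p53 targets; by fry it ended all 9. It changed gene calls where given beside them. The count of genes that differ among clones was 1641, and 2464 with no filter and 1 without the group term, where the effect of DOX enters the spread. The share of called genes that moved in the same direction in 3 clones was 100% in the main analysis, a share that the selection of called genes nearly fixes. Of single named genes, 1638 results kept their side of the threshold, 378 passed it and 317 lost it over all settings, and of single lists 514, 22 and 51. No named gene changed direction. No list called in the main or the other setting changed its test direction. The medians of the goblet, absorptive and histone lists changed sign with single libraries left out. At this depth, ZEB2, SNAI2 and TWIST1 had too few counts to be tested.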

Other observations

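The tests of ZEB1 level and of mixed cells in clone 3, of the interferon-stimulated genes by clone, of blocks with other pairings, and of gene families by symbol were chosen only after the results were seen.

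Mitochondrial ribosomal proteins, which translate the mRNAs of mitochondria, were slightly lower with DOX. Of 28 small-subunit genes (symbols starting with MRPS) none passed by edgeR (9 at an unadjusted p under 0.05, 1 by DESeq2), while 9 fell and none rose with the clone as a block, 18 were lower in each of the 3 clones, and the median log2 change was -0.27 (-0.19 with total counts). Of 47 large-subunit genes (MRPL) none passed by edgeR (9 at an unadjusted p under 0.05, 2 by DESeq2), 12 fell and 1 rose with the block, and the median was -0.21 (-0.13 with total counts). Of 22 nucleoporin genes (NUP), none passed by edgeR (7 at an unadjusted p under 0.05, 1 by DESeq2), 8 fell with the block and the median was -0.31 (-0.23 with total counts). Among 197 families defined by symbol, camera gave adjusted p-values of 0.0032, 0.0069 and 0.0032 for these. In all 9 families passed, 8 with a lower median and 1 with a higher one; the others were KRT, with the lowest adjusted p of 2.2e-04, MCM, RRP, TIMM and PSMD, and, with the higher median, IFI. None passed with an estimated correlation (lowest adjusted p = 0.885). Effects of DOX itself and of ZEB1 on these families cannot be told apart.

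None of the other 9 splits of the 6 libraries into 3 and 3 called a gene, where the real split called 292 (1 of 10 splits as large; up to 806 genes at an unadjusted p under 0.05 in the others). With the clone as a block, none of the 3 exchanges of DOX labels within a clone called a gene, where the real labels called 2638 (1 of 4; up to 35 at an unadjusted p under 0.05). With 10 splits and with 4 exchanges, a share under 0.05 cannot be reached. In every other split or exchange both sides hold mDOX and pDOX libraries, so the effect of DOX enters the spread. The lack of calls there was therefore likely from the start and does not measure what chance alone would call. For the gene lists, 3 of the 10 splits gave at least the 13 of the real split, and the highest other gave 16. The 6 splits that keep the libraries of 2 clones together gave 16, 13, 10, 7, 7 and 6 lists, and the 3 other splits that part every clone gave 12, 7 and 1.

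Clone 3 changed less than clones 1 and 2, with a slope of 0.67 on clone 1 over the 292 genes. Uninduced cells in the clone 3 culture would need a share of 21.9% to be the whole cause. Of 122 fallen genes, 8 (6.56%) kept less in clone 3 than that share, beyond counting error. S100A14, for example, kept 7.33% of its mDOX level (upper limit 9.17%). These 8 are mainly genes of largest fall, and their limits leave out variation between cultures. The values therefore go against that share for these 8 genes only, and a smaller share remains open. A lower ZEB1 level cannot be told apart from the other differences between clones: the ZEB1 level with DOX was 0.930 times that of clone 1 (95% counting interval 0.826 to 1.05), while the ZEB1 fold over the clone's own mDOX library was the lowest in clone 3, at 10.3. Against a response in proportion to the counted ZEB1, clone 2 had 215 CPM of ZEB1 with DOX and clone 1 had 76.8 CPM, with a slope of clone 2 on clone 1 of 1.02. Since transgene mRNA may be missed by the 3' counts, these ZEB1 values may not give the ZEB1 dose of a clone. The greater depth of the pDOX library of clone 3 was examined by thinning, over the 292 genes. With all libraries thinned to 6225188 counts, the slope on clone 1 was 0.669 (0.671 before) and that on clone 2 was 0.641 (0.645 before). The smaller change of clone 3 thus remained at equal depth. CPM values are already scaled for depth, so thinning could move these slopes little and decides no more than that. A different answer of clone 3 to ZEB1 stays untested.

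Interferon-stimulated genes were higher with DOX in each clone, but single genes of the list passed only with the clone as a block. The rise did not depend on which scaling was used. The median log2 change of the list was 1.16 with TMM, 1.15 with DESeq2 size factors and 1.22 with total counts. These scalings differ little, with medians over all tested genes of 0.018, 0.006 and 0.095 in that order. The comparison could therefore hardly have come out otherwise and decides no more than that. That clone 3, which has the highest levels, carries the change alone is argued against: the lower of the medians in clones 1 and 2 was 0.81, with 18 and 19 of 19 genes higher with DOX. DOX itself may raise these genes without ZEB1, and this cannot be told apart from the transgene, because 0 samples without the transgene were treated with DOX among the libraries used here. The hypothesis that ZEB1 raises the interferon-stimulated genes therefore stays open.

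The clone block raised the count of changed genes from 292 to 2638. A candidate explanation is that differences shared by both libraries of a clone widen the spread when the clones are pooled. The 2 pairings that match libraries of different clones throughout called 21 and 3 genes, and the 3 that keep 1 clone paired with itself called 210, 112 and 0 (over these 5, between 1691 and 2437 at an unadjusted p under 0.05, against 4122 with the true pairs), which fits this explanation; with 6 pairings, a share under 0.05 cannot be reached. Whether the clone itself or its handling as a replicate is what the libraries share was not tested. In the simulated data, where each changed gene had the same fold in all clones, 8.88% of the calls with the block were unchanged genes.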
